A study of Homo sapiens with 6 samples.

How the data were processed

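Messenger RNA was sequenced from 6 samples of Kasumi-1, an established human acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion. Per the labels, 3 samples expressed a doxycycline-inducible hairpin RNA against luciferase (control) and 3 a hairpin against FBL (FBL knockdown), and all received 100 ng/ml doxycycline for 72 h. Total RNA went into libraries made with a NEBNext Ultra RNA kit, per the labels' protocols. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Mass spectrometry of newly made proteins, which the series' design text mentions, was not analysed here.

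The authors deposited a table of whole-number counts per Ensembl gene for the 6 libraries, with 31966 genes and the gene length in bases. The submitters' processing notes name cutadapt 1.18, HISAT2, featureCounts, edgeR and the build GRCh38. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of near-identical genes may therefore be split, and reads of a gene and its antisense partner cannot be told apart. A second deposited table holds RPKM values. Recomputing them from the counts, the lengths and library totals scaled by the trimmed mean of M values (TMM) gave all 191796 deposited RPKM values within a relative tolerance of 1e-06, so the 2 tables hold the same measurement. Every gene row named a gene, and 0 columns were left unused.

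Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The counts were filtered with filterByExpr at its default settings (a minimum count of 10 and a minimum total of 15), which left 18486 of 31966 genes, and scaled by TMM. The groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) on group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. A fold change is knockdown against control, and CPM values, from the cpm function of edgeR, are counts relative to the TMM-scaled library total. Positions and gene types came from GENCODE v29 on GRCh38, matched by Ensembl identifier for 31848 of the 31966 genes.

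A set of 40 gene lists (1025 genes, of which 984 were found in the table and 4 of those by a current symbol) was written from general knowledge, and FBL is in none of them. The 39 lists with at least 3 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way, were alternatives. The grouping, the tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

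The rule for named genes was as follows. FBL came first. Among genes past the threshold with a mean of at least 10 CPM, groups that did not overlap and an established symbol, the 12 largest changes in each direction were named, plus the 4 with the smallest p in each direction that were not already taken. From each list came up to 4 members with the largest change among those past the threshold at a mean of at least 1 CPM. RUNX1, RUNX1T1, KIT, CD34 and MYC were always given. A few genes that the rule names, and 1 of the lists, are left out of the text. Where no member of a list passed, the 2 with the smallest p were named.

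The alternatives chosen in advance were other scalings in edgeR (RLE, upper quartile, library size only), no filter and a stricter filter on low counts (at least 1 CPM in 3 libraries and a mean of at least 5 CPM), DESeq2, limma voom, the legacy dispersion of edgeR, and a block for the replicate number. Others were the omission of each library, the omission of the 20 highest and the mitochondrial genes, thinning to the smallest library, and limma-trend on log2(RPKM + 1) or log2(RPKM + 0.1), where the pseudocount understates changes of low genes. A per-library correction for GC content, a fit without the 2 libraries richest in GC-rich transcripts and a fit of protein-coding genes alone were added after the data were seen.

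The tests were tried on simulated data drawn from the real means and library sizes, in which 200 genes were changed. In that simulation of knockdown against control, edgeR's test recovered 67% of genes changed 1.5-fold and 100% of those changed 2-fold. It covered 18258 genes and had a false share of 6.7%. The changed genes were drawn from those above 1 CPM, so recovery of weaker genes was not tested. Far more genes were called in the real data than were changed here, so scaling under widespread change was not tested either. Camera called the 1 shifted list and 0 of the others among 40 simulated lists. Genes were simulated independently of each other, so this does not test camera's false calls on lists of correlated genes. Total counts ran from 85556322 to 103148412 per library, and the chi-square per gene between replicates of a group was at least 33.7, far above sampling noise, so no library was a copy of another. Intervals and SEs do not cover errors in how reads were assigned to genes.

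For a scan of 3' untranslated regions (3' UTRs), the longest annotated 3' UTR of at least 50 bases was taken per gene from GENCODE v29 for 10606 of the 10731 tested protein-coding genes at 1 CPM or more. Log2 fold changes were adjusted for the length and GC content of the 3' UTR, clipped at the outer 0.5% in each tail, and compared between genes with and without each 7-base sequence present in at least 50 genes. A planted sequence was the strongest hit in simulated data. The scan used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.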

Results

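To learn how the messenger RNAs of a leukaemia line respond to loss of fibrillarin, RNA was sequenced from Kasumi-1 cells that expressed a hairpin against luciferase (control, n = 3) or against FBL (FBL knockdown, n = 3). FBL encodes fibrillarin, the enzyme of the box C/D small nucleolar ribonucleoproteins that places 2'-O-methyl groups on ribosomal RNA. Doxycycline was given to both groups at 100 ng/ml for 72 h. The deposited total counts were 88541034, 103148412 and 100083599 in the control libraries and 95023102, 93613475 and 85556322 in the knockdown libraries. On the log2 CPM of the tested genes, the first principal component held 60% of the variance and separated the groups, and the second held 17.9%. Mitochondrial ribosomal RNA took 1.36% ± 0.05 of counts in controls and 2.23% ± 0.25 in knockdown libraries (SD, n = 3 each; 2-sided exact permutation test p = 0.1, the smallest that 3 against 3 can give). All transcripts of the mitochondrial genome together took 13.8% ± 1.4 and 16.8% ± 2.0 (SD, n = 3 each; 2-sided exact permutation test p = 0.2).

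The targeted transcript was examined first. FBL (ENSG00000105202, GRCh38 chromosome 19, 39834458 to 39846414, minus strand) stood at 580, 550 and 544 CPM in the control libraries and at 54.0, 32.4 and 44.9 CPM in the knockdown libraries. The means were 558 ± 19.6 and 43.8 ± 10.8 CPM (SD, n = 3 each), a 12.7-fold lower level. The log2 fold change was -3.67 ± 0.16 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.93e-06). Every library matched its label in this respect.

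**Figure D1:**
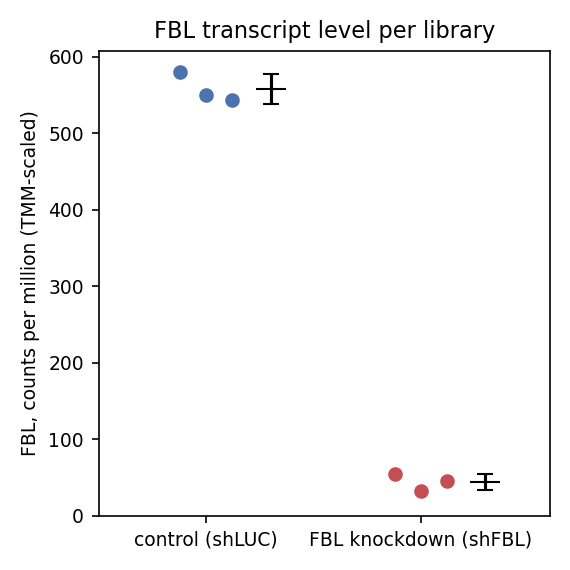
FBL transcript level in TMM-scaled CPM (vertical axis, from 0) for the 3 control and 3 FBL knockdown libraries, 1 point per library. The bars beside the points show the mean and SD, and the knockdown libraries sit between 32.4 and 54.0 CPM, all below the controls.

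The comparison of knockdown with control over all genes asked which transcripts differed once FBL was depleted. Among genes that met the naming rule, with a mean of at least 10 CPM over all libraries, the largest falls after FBL were in SDHA and MCM7. SDHA, a subunit of respiratory complex II, was at -1.69 ± 0.12 (log2 fold change ± SE, n = 3 against 3). MCM7, a subunit of the replicative helicase on chromosome 7 (100092728 to 100101940), was at -1.63 ± 0.12. MCM7 stood at 740 ± 73.3 CPM in controls and 240 ± 33.1 CPM in knockdown libraries (SD, n = 3 each). The chaperones HSPA1A (-1.61 ± 0.12) and HSP90AB1 (-1.34 ± 0.15), the ATPase VCP (-1.53 ± 0.16) and the mitochondrial protease LONP1 (-1.44 ± 0.13) fell as well. So did the hexokinase HK1 (-1.57 ± 0.17), the glycogen synthase GYS1 (-1.41 ± 0.10), the uridine-cytidine kinase UCK2 (-1.38 ± 0.09), the RNA-binding protein TAF15 (-1.48 ± 0.17), the nucleolar protein nucleolin (NCL, -1.33 ± 0.19) and the alanyl-tRNA synthetase AARS1 (-1.32 ± 0.13). With small p-values MAGED1 (-1.31 ± 0.09), OSGEP (-1.29 ± 0.09), SYCP3 (-1.11 ± 0.08) and WDR61 (-1.10 ± 0.08) were also lower. In this set of lower genes the adjusted p of edgeR's quasi-likelihood test ranged from 1.39e-05 for UCK2 to 0.000453 for NCL.

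Among genes that rose and met the same rule, COL2A1, a fibrillar collagen gene on chromosome 12 (47972965 to 48004554), led with 2.46 ± 0.14 (log2 fold change ± SE). It went from 3.86 ± 0.73 to 21.3 ± 1.9 CPM (SD, n = 3 each). The neuronal pentraxin receptor NPTXR (1.98 ± 0.09), the protocadherin DCHS1 (1.82 ± 0.12), the amino acid transporter SLC43A2 (1.78 ± 0.11), DISP2 (1.64 ± 0.15) and the membrane-bound transcription factor MYRF (1.58 ± 0.11) followed. Further increases were found for CCDC92 (1.56 ± 0.12), ENHO (1.55 ± 0.14), the red-cell membrane skeleton protein DMTN (1.55 ± 0.11), the aquaporin AQP3 (1.53 ± 0.10) and the JNK scaffold MAPK8IP1 (1.53 ± 0.15). With small p-values ETNK2 (1.39 ± 0.10), TSPAN33 (1.34 ± 0.08), RAMP2 (1.33 ± 0.09) and RAB40B (1.33 ± 0.09) rose too. RNU1-4, a U1 small nuclear RNA gene, was higher at 1.80 ± 0.17, but its near-identical copies can share reads, and so can the SDHA pseudogenes and the HSPA1A and HSPA1B pair, so these values are uncertain. For the higher genes the adjusted p of edgeR's quasi-likelihood test ranged from 3.93e-06 for NPTXR to 7.36e-05 for MAPK8IP1. All 32 genes named here had groups that did not overlap, which the naming rule required. The 3' UTRs of HK1, GYS1, UCK2, ENHO, DMTN and ETNK2 hold a 7-base sequence of FBL mRNA that is taken up in the closing section. Among the list members named in the text, it is also held by DKC1, UBTF, RPS29, SLC7A1, BCL2L2, SOX4, EGR1, PAX5, HSP90AA1, MRPS27, LSS, TFEB and HILPDA.

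The genes that define these cells moved less. RUNX1 (0.15 ± 0.09, adjusted p = 0.217), RUNX1T1 (0.06 ± 0.11, adjusted p = 0.698) and KIT (-0.14 ± 0.11, adjusted p = 0.372) did not pass edgeR's quasi-likelihood test. The counts do not separate the fusion transcript from the intact genes. The stem cell antigen CD34 rose (0.66 ± 0.13, edgeR adjusted p = 0.0024) at a low level of 3.29 CPM over all libraries. MYC fell slightly (-0.27 ± 0.09, edgeR adjusted p = 0.0426), and it lost its call in 10 of the 14 alternative settings tried.

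In total 6061 of 18486 tested genes (32.8%) passed the edgeR quasi-likelihood test, 2920 higher and 3141 lower. Under upper-quartile scaling 3597 were higher and 2528 lower, so that 58.7% of calls were higher in place of 48.2%. By limma-trend 1754 were higher and 2562 lower on log2(RPKM + 1), or 40.6% higher, and 1747 and 2562 on log2(RPKM + 0.1), or 40.5% higher. Groups did not overlap for 5929 of the called genes and for 8351 of all tested genes, or 45.2%, where chance gives 10%. At least a 2-fold difference was seen for 973 called genes, of which 699 were higher and 274 lower. The higher ones were mostly weak: 425 lay under 1 CPM and 225 between 1 and 10 CPM, while 0 of the 1724 genes at 100 CPM or more rose 2-fold and 23 of those fell 2-fold. The count of called genes dropped to 3923 without FBL knockdown replicate 2 and to 4017 without FBL knockdown replicate 3. With the stricter filter on low counts the 2-fold count was 215 (110 higher, 105 lower). On the RPKM values it was 91 with a pseudocount of 1 (42 higher, 49 lower) and 281 with 0.1 (156 higher, 125 lower), so the excess of higher genes was not kept in these settings at its size or, with a pseudocount of 1, in its direction.

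**Figure D2:**
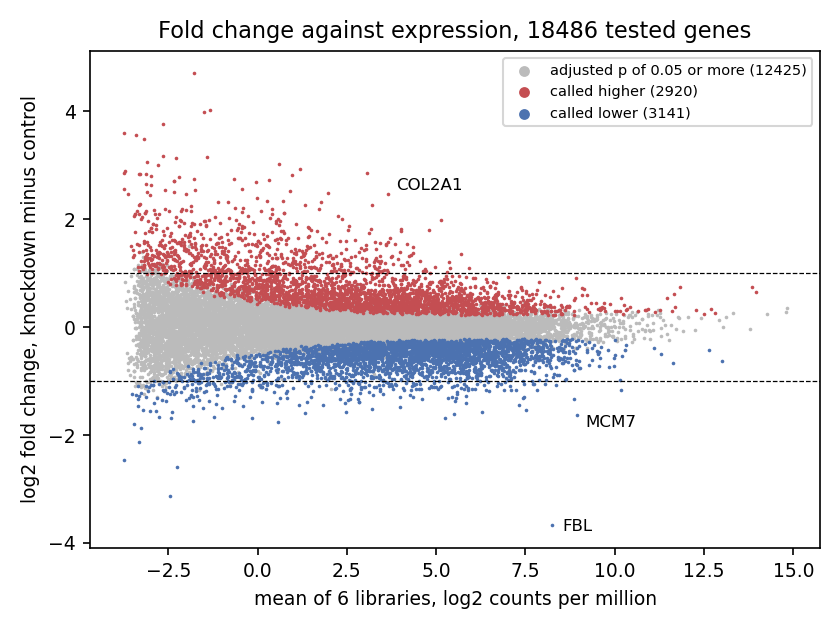
Log2 fold change of knockdown against control (vertical axis) against the mean log2 CPM of the 6 libraries (horizontal axis) for the 18486 tested genes, 1 point per gene. Red points are the 2920 genes called higher and blue points the 3141 called lower, dashed lines mark a 2-fold difference, and the 2-fold higher genes crowd at the weak end.

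The 40 fixed gene lists were then compared with all other genes, to describe which processes the changed genes belonged to. Direction varied with abundance over all tested genes. Of 5179 genes under 1 CPM, 697 were called higher and 270 lower. From 10 to 100 CPM, 934 of 5485 were higher and 1520 lower, and at 100 CPM or more 234 of 1724 and 479. The lists were not matched for abundance. With the stricter filter on low counts, 14 of 35 lists were called lower and 3 higher. Of 39 lists tested, 17 were called by camera, 16 lower and 1 higher. With an estimated correlation 0 were called by camera (8 at an unadjusted p under 0.05), and fry called 26. The estimate was below 0.01 for the called LSC17 (-0.033), cholesterol (-0.0265) and integrated stress response (-0.0102) lists. So it was for other ribosomal RNA enzymes (0.00497) and mitochondrial ribosomal proteins (0.00786). Camera's adjusted p of these still rose to 0.137, which argues against higher correlation of members as the cause of their lost calls. The other called lists had estimates from 0.0467 to 0.554, so that cause stays open there. Other causes were not tested. With the same preset correlation, another split of these 6 libraries into 3 and 3, with both groups on each side, gave 16 called lists. In the counts below, the number in brackets is the count adjusted over the list alone, medians are log2 fold changes, and members are given as log2 fold change ± SE. Some named members lost their call in part of the 13 or 14 alternative settings tried: NUFIP1 in 8, SDC1 in 7, BNIP3L in 6, JUNB and SNHG1 in 5, BIK, EPOR and RPS9 in 4, and FOSB, H2AC6, ICAM1, KIF23, PIH1D1, RPL41 and RPLP0 in 3. HILPDA, MVD, NFKB1 and TPSB2 lost it in 2, and CD247, CKAP5, NAF1, SLC36A4 and UBTF in 1.

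Genes of the G1/S transition and DNA replication had the smallest p of the lists: 32 of 45 members fell [33], 0 rose, and the median was -0.54 (camera adjusted p = 9.85e-16, adjusted p = 0.29 with an estimated correlation). MCM7 had the largest fall, and the maintenance methylation factor UHRF1 (-1.30 ± 0.10), the ribonucleotide reductase subunit RRM1 (-1.15 ± 0.19) and the histone chaperone NASP (-1.12 ± 0.11) came next. The 10 members without the sequence GGAGAT of FBL mRNA in the transcript parts searched had a median of -0.13. Of 55 G2/M genes 25 fell [27] and 0 rose [1], with a median of -0.32 (camera adjusted p = 2.85e-05, adjusted p = 0.499 with an estimated correlation). Examples were the spindle factor TPX2 (-1.06 ± 0.14), KIF23 (-0.74 ± 0.22), CKAP5 (-0.71 ± 0.17) and the tubulin TUBB4B (-0.70 ± 0.09). Among MYC and MYC-responsive genes 22 of 28 fell [25] and 0 rose, with a median of -0.46 (camera adjusted p = 7.61e-10, adjusted p = 0.137 with an estimated correlation). They included the co-chaperone FKBP4 (-0.98 ± 0.09), the spermidine synthase SRM (-0.96 ± 0.13), APEX1 (-0.94 ± 0.09) and the mitochondrial chaperonin HSPD1 (-0.88 ± 0.14). Replication-dependent histone genes were not called as a list, with 1 member higher [0] and 3 lower [1] of 43 and a median of -0.21 (camera adjusted p = 0.266). H2AC6 was higher at 0.41 ± 0.11.

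The partners of fibrillarin in the box C/D core did not pass: 0 of 3 changed, NOP56 was at -0.20 ± 0.13 and NOP58 at -0.23 ± 0.16, and the median was -0.21 (camera adjusted p = 0.572). Without control replicate 2 both fell past the threshold, NOP56 at -0.31 and NOP58 at -0.39 (edgeR adjusted p = 0.0272 and 0.0177). Factors that assemble box C/D particles fell in 5 of 8 cases [5], among them the AAA ATPases RUVBL2 (-0.90 ± 0.14) and RUVBL1 (-0.78 ± 0.10), NUFIP1 (-0.48 ± 0.15, call lost in 8 of 13 settings) and PIH1D1 (-0.34 ± 0.08, lost in 3 of 14). Their median was -0.31 (camera adjusted p = 0.0138, adjusted p = 0.29 with an estimated correlation). Of 6 box H/ACA genes, whose particles guide pseudouridylation, 3 fell [3], namely GAR1 (-0.90 ± 0.10), the pseudouridine synthase DKC1 (-0.61 ± 0.10) and NAF1 (-0.40 ± 0.10), with a median of -0.26 (camera adjusted p = 0.0184, adjusted p = 0.29 with an estimated correlation). Other enzymes that modify ribosomal RNA fell in 8 of 15 cases [9] and rose in 2 [2], with a median of -0.34 (camera adjusted p = 0.0015, adjusted p = 0.137 with an estimated correlation). FTSJ3 (-1.20 ± 0.15), NOP2 (-0.93 ± 0.12), MRM1 (-0.81 ± 0.14) and the acetyltransferase NAT10 (-0.79 ± 0.11) fell.

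Ribosome assembly factors fell in 48 of 79 cases [53] with 0 higher and a median of -0.47 (camera adjusted p = 1.35e-12, adjusted p = 0.29 with an estimated correlation). BMS1 (-1.40 ± 0.24), nucleolin, NOLC1 (-1.14 ± 0.14) and UTP3 (-1.13 ± 0.15) had the largest changes, and BMS1 has pseudogene copies that can share its reads. In the RNA polymerase I machinery 7 of 15 members fell [9] and 1 rose [3], with a median of -0.28 (camera adjusted p = 0.0458, adjusted p = 0.499 with an estimated correlation). Camera lost this call without control replicate 1 (adjusted p = 0.0687), without FBL knockdown replicate 1 (adjusted p = 0.0754) and in 4 other alternatives. The falls included the largest subunit POLR1A (-0.95 ± 0.13), POLR1C (-0.65 ± 0.11), POLR1B (-0.51 ± 0.09) and the ribosomal DNA transcription factor UBTF (-0.46 ± 0.11). Of the ribosomal protein genes of the small subunit 7 of 32 rose [6] and 1 fell [1], with a median of 0.15 (camera adjusted p = 0.0831). Camera called this list higher without FBL knockdown replicate 1 (adjusted p = 0.0495), under upper-quartile scaling (0.0481), without a filter (0.0405), with the stricter filter (0.0267) and after a GC correction (0.0213), and fry did too (0.0297). In the large subunit 9 of 47 rose [8] and 1 fell [1], with a median of 0.03 (camera adjusted p = 0.337). RPS27 (0.44 ± 0.08), RPS29 (0.42 ± 0.09), RPS20 (0.38 ± 0.08), RPL39 (0.59 ± 0.13), RPL41 (0.37 ± 0.10) and RPLP0 (0.34 ± 0.09) rose, whereas RPS9 (-0.43 ± 0.12) and RPL3 (-0.42 ± 0.08) fell. These values are uncertain, since processed pseudogenes took 5.4% to 6.5% of counts per library and the RPLP0 copy RPLP0P6 alone stood at 3312 CPM beside 6690 CPM for RPLP0. Host genes of small nucleolar RNAs rose in 7 of 16 cases [8] and fell in 1 [1], with a median of 0.24 (camera adjusted p = 0.0791, and 0.0129 without FBL knockdown replicate 1). ZFAS1 (0.78 ± 0.14), SNHG1 (0.47 ± 0.14) and SNHG29 (0.38 ± 0.09) rose and SNHG3 (-0.51 ± 0.09) fell.

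Further lists concern protein synthesis. Of 37 translation initiation and elongation factors 19 fell [20] and 0 rose [1], with a median of -0.32 (camera adjusted p = 2.37e-05, adjusted p = 0.355 with an estimated correlation). The scaffold EIF4G1 (-1.17 ± 0.12), EIF1AX (-0.91 ± 0.12), EIF2B5 (-0.88 ± 0.09) and EIF2S1 (-0.67 ± 0.10) were among them. Aminoacyl-tRNA synthetases fell in 16 of 20 cases [18] with 0 higher and a median of -0.53 (camera adjusted p = 7.19e-08, adjusted p = 0.29 with an estimated correlation), and beside AARS1 the largest falls were in GARS1 (-1.14 ± 0.16), YARS1 (-0.94 ± 0.10) and HARS1 (-0.83 ± 0.10). Mitochondrial ribosomal proteins fell in 19 of 52 cases [19] with 0 higher and a median of -0.23 (camera adjusted p = 0.000479, adjusted p = 0.137 with an estimated correlation), such as MRPS27 (-1.25 ± 0.09), MRPL3 (-0.71 ± 0.09), MRPS25 (-0.68 ± 0.08) and MRPL28 (-0.53 ± 0.10). Amino acid transporters were mixed, with 5 of 18 higher [6] and 4 lower [7], and camera placed them higher (adjusted p = 0.712) although their median was -0.20. Beside SLC43A2, SLC36A4 (0.67 ± 0.17) and SLC1A4 (0.64 ± 0.08) rose and SLC7A1 (-0.54 ± 0.10) fell.

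Lists of stress and chaperone genes were compared next. Heat shock chaperones fell in 12 of 14 cases [12], with 0 higher and a median of -0.61 (camera adjusted p = 9.73e-09, adjusted p = 0.239 with an estimated correlation). After HSPA1A, HSPA1B (-1.39 ± 0.14), HSP90AB1 and HSP90AA1 (-0.85 ± 0.14) had the largest falls. Of 20 genes of the unfolded protein response and the endoplasmic reticulum chaperones 14 fell [15] and 1 rose [1], with a median of -0.39 (camera adjusted p = 2.87e-05, adjusted p = 0.137 with an estimated correlation). HSPA5, the main chaperone of that compartment, fell by 1.09 ± 0.10, DNAJB11 by 0.74 ± 0.10, SDF2L1 by 0.72 ± 0.16 and MANF by 0.66 ± 0.09. Targets of the integrated stress response fell in 9 of 20 cases [10] and rose in 1 [1], with a median of -0.24 (camera adjusted p = 0.0025, adjusted p = 0.137 with an estimated correlation). The serine synthesis enzymes PSAT1 (-1.04 ± 0.09) and PHGDH (-0.81 ± 0.09), CTH (-0.96 ± 0.17) and the glutathione-degrading enzyme CHAC1 (-0.72 ± 0.11) were lower. In the BCL2 family 3 of 14 rose [4] and 4 fell [4], with a median of -0.03, or 0.03 under upper-quartile scaling (camera adjusted p = 0.934). The pro-apoptotic BMF (1.06 ± 0.10) and BIK (0.58 ± 0.19) rose, and the anti-apoptotic BCL2L2 (-0.69 ± 0.12) and BCL2L1 (-0.57 ± 0.10) fell.

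In metabolism, 13 of 18 glycolysis genes fell [13] and 1 rose [1], with a median of -0.51 (camera adjusted p = 3.93e-07, adjusted p = 0.239 with an estimated correlation). After HK1 came the glucose transporter SLC2A3 (-1.08 ± 0.10) and PGK1 (-0.98 ± 0.09), and the neuronal enolase ENO2 rose (0.96 ± 0.14). Cholesterol biosynthesis genes fell in 11 of 23 cases [11] and rose in 2 [2], with a median of -0.23 (camera adjusted p = 0.0041, adjusted p = 0.137 with an estimated correlation). FDPS (-0.96 ± 0.08), MVD (-0.71 ± 0.17) and LSS (-0.58 ± 0.10) were among them. Nuclear genes of oxidative phosphorylation were mixed, with 6 of 49 higher [6], 10 lower [10] and a median of -0.03, or 0.03 under upper-quartile scaling (camera adjusted p = 0.262). SDHA, ATP5F1A (-0.75 ± 0.08) and NDUFS1 (-0.59 ± 0.13) fell. Of 13 messenger RNA genes of the mitochondrial genome 1 rose [1], MT-ND3 at 0.53 ± 0.11, with a median of 0.19 (camera adjusted p = 0.188, but 0.0215 without control replicate 2 and 0.0058 without FBL knockdown replicate 3). Hypoxia targets had 4 of 13 members higher [4], 1 lower [1] and a median of 0.24 (camera adjusted p = 0.0791, fry adjusted p = 0.0105), with NDRG1 (0.72 ± 0.08), BNIP3 (0.51 ± 0.09) and BNIP3L (0.38 ± 0.12) higher and HILPDA (-0.34 ± 0.08) lower. Lysosome and autophagy genes had 7 of 31 higher [7] and 7 lower [7], with a median of 0.14 (camera adjusted p = 0.273, fry adjusted p = 0.00817). The transcription factor TFEB (1.15 ± 0.14), the cathepsin CTSB (0.68 ± 0.08) and WIPI1 (0.51 ± 0.10) rose and SQSTM1 (-0.54 ± 0.09) fell.

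**Figure D3:**
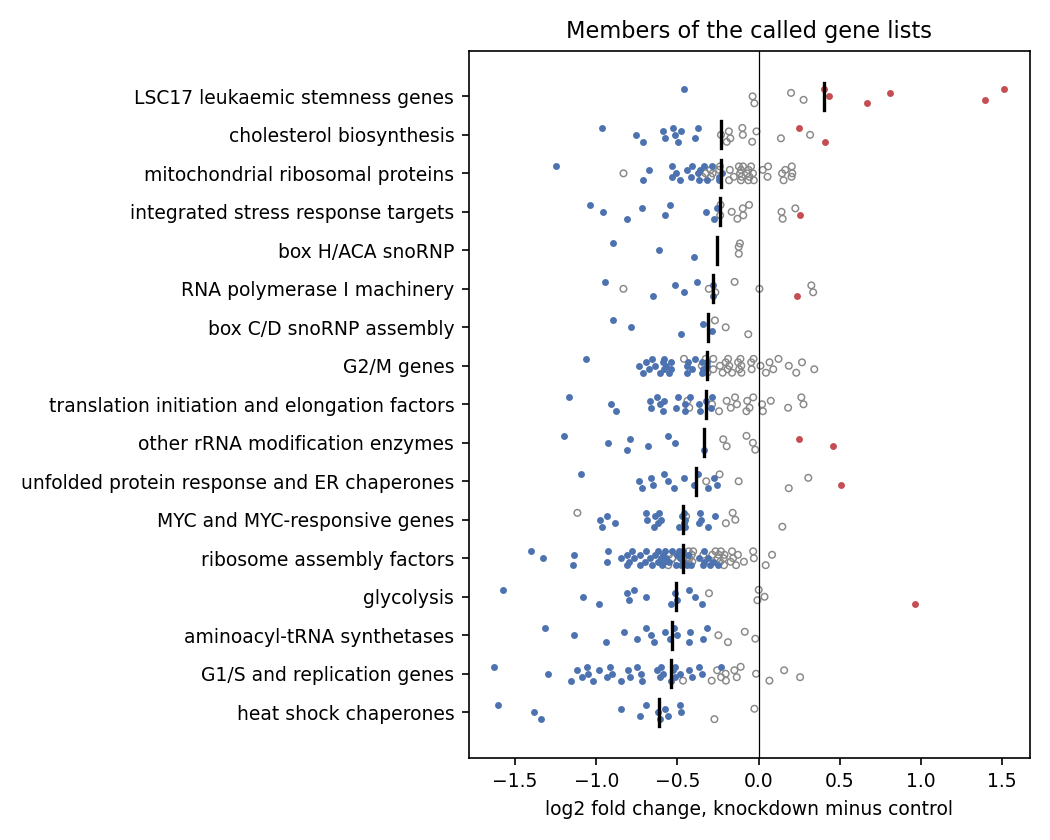
Log2 fold change of knockdown against control (horizontal axis) of the tested members of the 17 lists called by camera (vertical axis), 1 point per gene. Filled points passed edgeR's test, blue lower and red higher, open points did not, and the black bar is the list's median, from -0.61 for heat shock chaperones to 0.40 for the LSC17 genes.

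As the series concerns stemness, lists of stem cell and differentiation genes were compared too. The genes of LSC17, a published expression score of leukaemic stem cells, formed the 1 list called higher: 6 of 11 tested members rose [7], 1 fell [1], and the median was 0.40 (camera adjusted p = 0.000879, adjusted p = 0.137 with an estimated correlation). The list was tested without the weights of the published score and their signs, so whether the score itself rose or fell was not tested. SMIM24 (1.51 ± 0.14), NYNRIN (1.39 ± 0.11) and CPXM1 (0.81 ± 0.13) rose with CD34. SMIM24 and CD34 were weak, at 2.99 and 3.29 CPM over all libraries. Regulators of haematopoietic stem and progenitor cells had 7 of 24 higher [7], 3 lower [3] and a median of 0.04 (camera adjusted p = 0.712). HLF (0.85 ± 0.15) and BMI1 (0.62 ± 0.14) rose, and LMO2 (-0.60 ± 0.08) and SOX4 (-0.56 ± 0.10) fell.

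Granulocytic genes had 5 of 18 higher [5] and 4 lower [4], and camera placed them higher (adjusted p = 0.572) although their median was -0.12. MS4A3 (1.05 ± 0.15) and the receptor CSF3R (0.69 ± 0.11) rose, and the repressor GFI1 (-0.45 ± 0.07) and the protease CTSG (-0.43 ± 0.08) fell. Monocyte and macrophage genes had 4 of 16 higher [4], 3 lower [3] and a median of 0.16 (camera adjusted p = 0.626), with CSF1R (0.93 ± 0.14) and LGALS3 (0.54 ± 0.10) higher and EGR1 (-0.89 ± 0.13) and FCGR1A (-0.66 ± 0.13) lower. Of 8 mast cell, basophil and eosinophil genes 3 rose [3], with a median of 0.32 (camera adjusted p = 0.099, fry adjusted p = 0.00624), among them the tryptases TPSAB1 (0.87 ± 0.13) and TPSB2 (0.63 ± 0.17), which share reads and are uncertain. Of 6 erythroid and megakaryocytic genes 4 rose [4], with a median of 0.44 (camera adjusted p = 0.0791), among them NFE2 (0.63 ± 0.12), KLF1 (0.62 ± 0.13) and EPOR (0.36 ± 0.10). Camera called this list higher without control replicate 2 (adjusted p = 0.0177), without a filter (0.0405), with the stricter filter (0.0337), after a GC correction (0.0459) and without the 2 GC-rich libraries (0.0324), and fry did too (0.0297).

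Markers of cell types outside the culture were compared as well. T and NK cell markers had 2 of 5 higher [2] and 1 lower [1], with a median of 0.55 (camera adjusted p = 0.266, fry adjusted p = 0.0101), including CD8A (1.01 ± 0.14) and CD247 (-0.46 ± 0.10). B and plasma cell markers had 1 of 4 higher [2] and 1 lower [1], with a median of 0.04 (camera adjusted p = 0.266, fry adjusted p = 0.034), namely PAX5 (1.31 ± 0.12), a gene known to be active in leukaemias with the RUNX1-RUNX1T1 fusion, and SDC1 (-0.34 ± 0.10). Only 2 genes of the epithelial and fibroblast list were tested, too few for camera, and of these PDGFRA rose (0.96 ± 0.28) at 0.40 CPM.

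Interferon-stimulated genes had 2 of 32 higher [2] and 5 lower [5], with a median of -0.15 (camera adjusted p = 0.601). CMPK2 (1.08 ± 0.10) rose, and BST2 (-0.92 ± 0.15) and STAT2 (-0.70 ± 0.12) fell. NF-kB inflammatory genes had 1 of 17 higher [1], 6 lower [6] and a median of -0.31 (camera adjusted p = 0.441, fry adjusted p = 0.043), with TNFAIP2 (2.02 ± 0.18) higher and CXCL8 (-0.79 ± 0.13), NFKB1 (-0.42 ± 0.10) and ICAM1 (-0.41 ± 0.12) lower. Immediate-early genes had 2 of 15 higher [3], 5 lower [5] and a median of -0.14 (camera adjusted p = 0.266, and 0.0324 without control replicate 1). Beside EGR1, IER2 (-0.83 ± 0.12) and JUNB (-0.68 ± 0.20) fell and FOSB (0.60 ± 0.16) rose.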

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

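The per-library GC correction, the fit without the 2 libraries richest in GC-rich transcripts and the fit of protein-coding genes alone were tried only after the results had been seen. FBL stayed lower and past the threshold in every alternative run, with log2 fold changes from -3.85 to -3.49 when each library was left out. Counts of called genes ran from 3923 (without FBL knockdown replicate 2) and 4017 (without FBL knockdown replicate 3) to 6943 when libraries were left out, those with at least a 2-fold difference from 800 to 1197, and called lists from 17 to 19. In no alternative was a called gene called in the other direction. The 2-fold count fell to 215 with the stricter filter, which tests fewer weak genes, and to 91, 281 and 88 on log2(RPKM + 1), log2(RPKM + 0.1) and log2(RPKM + 1) without a filter, where the pseudocount shrinks changes of weak genes. Same-numbered libraries deviated from their group means with correlations of -0.284, -0.198 and 0.0449, so no pairing by number was seen. A pairing is not excluded, because the deviations also followed GC content, as given below, and were not corrected for it. With the replicate number as a block, 3833 genes were called, 865 of them at least 2-fold, and 17 lists. Camera with an estimated correlation called 0 lists (8 at an unadjusted p under 0.05) and fry 26, as weighed above. Fry added 9 lists, among them the small subunit ribosomal proteins, hypoxia, lysosome, NF-kB, mast cell, erythroid, T cell and B cell lists. Deviations of single libraries followed GC content (Spearman -0.691, 0.777 and -0.317 across genes in controls and 0.754, -0.645 and -0.377 in knockdown libraries), but the difference between groups did not (0.0123). After the GC correction 8457 genes, 989 at 2-fold, and 19 lists were called, and 99.77% of the called genes with a GC value kept call and direction, which argues against GC content as the cause of the calls. Without the 2 GC-rich libraries the counts were 7424, 1235 and 19, and for protein-coding genes 4979, 720 and 16. Of 2340 results for 169 named genes over the alternatives, 2239 kept direction and side of the threshold, 98 lost the call, 2 gained it and 1 reversed (RUNX1T1, -0.0328 without control replicate 2, and up to 0.127 without the other libraries in turn). The calls of 27 named genes were lost at least once, most often MYC (10 settings), NUFIP1 (8), SDC1 (7) and BNIP3L (6). Of the called lists, RNA polymerase I lost its call in 6 settings besides the estimated correlation (adjusted p = 0.0529 without TMM, 0.163 with the stricter filter, 0.0687 without control replicate 1, 0.0754 without FBL knockdown replicate 1, 0.0629 after the GC correction and 0.0838 among protein-coding genes), and box H/ACA with the stricter filter (0.0925). Camera gained 18 calls over 6 lists, among them the small subunit ribosomal proteins in 5 settings (adjusted p = 0.0213 to 0.0495), the erythroid list in 5 (0.0177 to 0.0459), snoRNA host genes in 4 (0.0129 to 0.0375), mitochondrially encoded genes in 2 (0.0058 to 0.0215) and immediate-early genes in 1 (0.0324). Lists that camera placed in the other direction were the granulocytic list (median -0.153 with the stricter filter, -0.237 without control replicate 1, and up to 0.0132 without the other libraries in turn), the monocyte list (0.0228 with the stricter filter) and the amino acid transporters (-0.191 without the 2 GC-rich libraries). The BCL2 family, with medians down to -0.15 when libraries were left out, did so without control replicate 2 (0.00162), control replicate 3 (-0.039), FBL knockdown replicate 3 (0.016) or the 2 GC-rich libraries (0.0197), and among protein-coding genes (-0.0259). None of these was called in either direction, and the cause was not tested. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 6061 genes, 973 at 2-fold and 17 lists, reached by 1 of the 10 splits in each case, and the highest of the other splits gave 0, 0 and 16. Those 9 splits had 89 to 1427 genes at an unadjusted p under 0.05 by edgeR. Each of them has libraries of both groups on each side, so the knockdown difference enters its spread. Their counts therefore do not show what chance alone would give. Thinning to the depth of the smallest library left 5997 genes called.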

Other observations

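The tests in this part were not among those chosen before the data were examined. The share of list members with 1 FBL 7-mer and the median of weakly expressed genes address patterns found in these results. Predictions for both, and for the scan of 3' UTRs, were written before each was run. The other tests were chosen only after the results had been seen. Further gene groups, picked after large changes in single members had been noticed, were described with camera over 6 added lists. Because the same data chose these lists, their p-values carry no error control and are descriptive only. Heterogeneous nuclear ribonucleoproteins, which bind and process pre-messenger RNA, fell in 18 of 19 cases with a median log2 fold change of -0.68 (camera adjusted p = 2.16e-14, adjusted p = 0.15 with an estimated correlation). HNRNPUL2 (-1.23 ± 0.11, SE), HNRNPM (-1.17 ± 0.12), HNRNPD (-0.93 ± 0.09) and HNRNPA2B1 (-0.91 ± 0.11) had the largest falls, and HNRNPUL1 was at -0.08 ± 0.09. Components of the U2 and U5 spliceosome particles fell in 16 of 18 cases with a median of -0.75 (camera adjusted p = 1.21e-12, adjusted p = 0.15 with an estimated correlation), including SF3B3 (-1.17 ± 0.15), the helicase SNRNP200 (-1.16 ± 0.16), U2AF1 (-1.15 ± 0.09), which has a near-identical copy, and PRPF8 (-0.74 ± 0.14).

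All 8 subunits of the cytosolic chaperonin CCT fell, from CCT5 at -1.02 ± 0.09 to TCP1 at -0.26 ± 0.08, with a median of -0.41 (camera adjusted p = 5.2e-05, adjusted p = 0.208 with an estimated correlation). Subunits of the 20S proteasome fell in 9 of 14 cases, with a median of -0.37 (camera adjusted p = 5.28e-05, adjusted p = 0.208 with an estimated correlation). Importins, exportins and RAN fell in 12 of 22 cases with 1 higher (camera adjusted p = 0.000547, adjusted p = 0.316 with an estimated correlation): KPNA1 was at -1.15 ± 0.11 and RAN at -0.87 ± 0.09, while XPO7 rose by 0.52 ± 0.08. The 12 tested subunits of the vacuolar proton pump had 2 lower and a median of -0.01 (camera adjusted p = 0.778).

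Of 16195 sequences of 7 bases tested in the 3' UTRs of 10606 genes, GGAGATG had the strongest tie to lower values: 1687 genes with it were 0.112 ± 0.011 (SE across genes) lower on the log2 scale than the rest (z = -9.85, -9.69 after the GC correction, Bonferroni threshold 4.66), and 5 of the next 6 sequences shared its core GGAGAT. Of these 5, AGGAGAT (z = -8.03) occurs in FBL mRNA, while TGGAGAT (z = -8.35), GGAGATT, GGAGATA and GGGAGAT do not. FBL mRNA holds 1045 of the 16195 sequences. GGAGATG occurs once in FBL mRNA, in coding exon 5 of 9 at chromosome 19, 39839196 to 39839202 (GRCh38). The difference deepened with the length of the match to FBL mRNA, from -0.087 ± 0.016 at 7 bases to -0.161 ± 0.030 at 9 and -0.250 ± 0.041 at 10 or more (115 genes). The difference was -0.126 to -0.097 in 9 of 9 pairs of a knockdown with a control library against -0.022 to 0.011 within groups. Between control libraries z ran from -0.87 to 1.74, but z still reached -5.49 between FBL knockdown replicates 2 and 1. These had the lowest and highest FBL of the knockdown libraries, at 32.4 and 54.0 CPM. As z over genes leaves out the spread between libraries, it overstates the evidence, also for CTTCGAA (208 genes 0.160 ± 0.030 higher in knockdown, z = 5.34, absent from FBL mRNA). A candidate explanation for GGAGATG is repression by the FBL hairpin through its seed, in the manner of a microRNA, but a motif unrelated to the hairpin cannot be told apart, because the FBL flanks ranked 3 of 253 flank pairs behind other A-rich flanks. The hairpin sequences are not given in the sources used here, so whether the genes with CTTCGAA rose in knockdown or were repressed in controls by the luciferase hairpin was not tested.

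GGAGATG lay in the 3' UTR of 489 of 2416 lower genes (20.2%), against 14.6% of other genes, while related sequences and sites elsewhere in transcripts stay open for the rest. For the G1/S, ribosome assembly and MYC-responsive lists, GC content as the cause is argued against by the GC correction, which left the smallest of their falls at 0.453. No single FBL 7-mer lay in the 3' UTRs of more than 43.9% of the members that fell. So no 1 such site in a member's own 3' UTR can account directly for all of these falls. The 43.9% belongs to the FBL 7-mer most common among those members, which 44.6% of other genes held. Whether GGAGATG was enriched among these members was not tested, so this share cannot decide on repression through it. Members with no GGAGAT in the transcript parts searched had medians of -0.289 for 30 ribosome assembly genes (95% bootstrap interval -0.385 to -0.214, 15 fell) and -0.530 for 8 MYC-responsive genes (-0.640 to -0.452, 7 fell). Members with it had -0.505 and -0.464. These values argue against direct repression through a member's own sites as the whole cause, but leave a share open for ribosome assembly. Whether members without such sites fell as an indirect effect of off-target repression was not tested. For G1/S the 10 such members had a median of -0.130 (-0.413 to 0.071) beside -0.624 for the others, too few to exclude seed repression there. These intervals resample genes, so they leave out the spread between libraries and the correlation of members. Transcript length was not adjusted for in these medians. Loss of FBL itself, which the design names, stays open for all 3 lists, and a second hairpin or a rescue would be needed to part it from off-target repression.

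The genes at least 2-fold higher were mostly weakly expressed. A uniform rise of background reads in the knockdown libraries would lift nearly all weak genes. A lift of over 0.3 on the log2 scale is argued against by the median of the 5179 tested genes under 1 CPM. That median was 0.096 (95% bootstrap interval over genes 0.076 to 0.118), with 697 of them called higher and 270 called lower. It was 0.104 under RLE and 0.160 under upper-quartile scaling, against medians of 0.001 and 0.059 for all tested genes. Under each scaling tried, the median of these weak genes lay above that of all tested genes, so a smaller rise stays open. Under 10 CPM 650 genes were 2-fold higher and 181 were 2-fold lower. Loss of FBL, which the design names, stays open and was not tested apart from the hairpin.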
